A study of Homo sapiens with 26 samples.

How the data were processed

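RNA from MCF-7 cells, an estrogen receptor-positive human breast cancer line, was measured on 26 Affymetrix expression arrays. They covered 5 groups. S0.5, the fulvestrant-sensitive parental line, had 6 arrays. The resistant sublines ICI164R1, ICI164R4, ICI182R1 and ICI182R6 had 5 arrays each, lettered a to e. Per the labels, the resistant cells were kept in 100 nM fulvestrant, a drug that binds the estrogen receptor and lowers its level, and were used within 10 passages. The treatment of the S0.5 cells before extraction is not stated, so the presence of the drug and the resistance of the cells cannot be told apart in these groups. The arrays are called biological replicates, but it is not stated that each came from a separate culture, so the p-values measure the spread between these arrays and no more. The growth protocol gives subline names that differ from the sample labels, which say ICI164R4, and the labels were used. Whether each array carries the right subline name cannot be told from the values, which limits every result for a single subline. There is 1 parental line, and no other resistant line from another parent.

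The deposited values are log2 RMA signal intensities per probe set, and the submitters' processing notes name Partek and RMA. Total RNA was labelled with biotin. Values ranged from 2.80 to 15.1. Whether all 26 arrays were normalized together is not stated. The table holds 54675 probe sets. Of these, 41091 were annotated to exactly 1 gene symbol, 1801 to several and 11777 to none, and the other 6 are control probe sets of actin and GAPDH. For each gene the probe set with the highest mean over the 26 arrays was taken among those annotated to that gene alone, which left 19775 genes. No filter on low values was applied. The genome build behind the annotation is not given in the sources used here, so no positions are given. Scan dates are not given either. Arrays have no counting depth, and their number limits the precision. No 2 arrays were copies of each other: the closest pair differed with an SD of 0.239 over the 54675 probe sets.

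A linear model with 1 mean per group was fitted to all 26 arrays with limma 3.58.1 in R 4.3.3, so that the groups shared an estimate of the spread for each gene. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested and a log2 fold change of at least 1 in either direction. The contrasts set each subline against S0.5, the mean of each pair of sublines with the same drug name (the ICI164 family and the ICI182 family) against S0.5, the mean of the 4 sublines against S0.5, the families against each other, and the sublines within a family against each other. Fold changes are log2 differences with the standard error (SE) of the fit, and group values are mean log2 intensity with the standard deviation (SD) between arrays. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, adjusted over the 23 lists within a contrast. With arrays left out or the values processed otherwise, camera used the preset correlation alone. The share of list members called was also counted with the p-values adjusted over the list alone. The lists were estrogen receptor and its targets, the cyclin D, CDK4/6 and RB axis, proliferation and E2F targets, pro-apoptotic genes, anti-apoptotic genes, receptor tyrosine kinases, their ligands, luminal markers, basal markers, mesenchymal genes, interferon-stimulated genes, MHC class I and antigen presentation, NF-kB targets, hypoxia and glycolysis, cholesterol biosynthesis, the unfolded protein response, Notch and Wnt signalling, cell adhesion and stemness markers, drug transport and metabolism, immediate early genes, and markers of fibroblasts, leukocytes and endothelium. They held 494 entries, of which 459 were measured. AR, STAT1, KRT17 and HMGCR were among the entries without a probe set annotated to that gene alone.

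The contrasts, tests, gene lists, a first group of other settings and the rule for naming genes were set before the data were examined. The rule always names CDK6, CDK4, CCND1, RB1, CDKN2A, ESR1, PGR, GREB1, TFF1, BCL2, EGFR and ERBB2. Among genes called in all 4 sublines with no resistant array inside the S0.5 range, it names the 12 highest and the 12 lowest. It names the 5 highest and 5 lowest called genes of each subline, the 8 highest and 8 lowest genes that separate all arrays of the families, up to 4 called genes in each direction between sublines of a family, and up to 4 members of each list by size of change. Genes named outside the rule are marked as chosen after their values were seen.

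The control probe sets on the array were used to look for technical groups of arrays. They separated the arrays into 2 sets that cut across the sublines. The set was not in the planned model, and a fit with the set as a fixed term (called the block) and fits within each set were added after the data were seen. The change of a gene named by the rule is given with its block value where the block ended the call, turned its direction or moved it by more than 1.5 times. Differences in control values were tested with an exact permutation test (two-sided), adjusted over the 8 tests.

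Tests on simulated data used groups of the same sizes and 200 changed genes of 19775. Calls recovered 41.8% to 56.7% of 2-fold changes, 94% to 100% of 4-fold changes and 97% to 100% of 8-fold changes, with 0 to 6 false calls per contrast. With a simulated effect of the array set, false calls numbered 1 to 75 without the block and 0 to 4 with it. That effect was put on fewer genes than the 3768 that differed between the sets within groups, in the block fit (limma adjusted p under 0.05, any fold). A shifted list was called by camera in 20 of 20 simulated data sets, and 2 of 440 tests of lists that shared no gene with it were called. Simulated genes varied independently, so this does not test camera at the preset correlation where genes of a list vary together.

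The other settings chosen beforehand were the mean of all probe sets of a gene, leaving out the 30 percent of genes lowest in mean, median centring, quantile normalization, a fold threshold of 1.5, the limma treat test at a log2 change of 1, an intensity trend with robust fitting, array weights, fits to the compared arrays alone, pooling sublines, subline as a random block, the replicate letter as a block, leaving out each subline, leaving out each array, and separate groups of 3 S0.5 arrays for overlaps. Settings added after the values were seen were the block, fits within a set, the block without S0.5 array 1, leaving out 3 ICI164 arrays, and the probe set with the highest group mean. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Probe sets annotated to several genes or to none were left out of the gene tests, since their signal cannot be assigned to 1 gene.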

Results

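Gene expression was measured in 4 MCF-7 sublines resistant to fulvestrant (ICI164R1, ICI164R4, ICI182R1 and ICI182R6, 5 arrays each) and in the sensitive parental line S0.5 (6 arrays). The series title names CDK6 and resistance to fulvestrant, so the main question was how the resistant sublines differed from S0.5, and in CDK6 among other genes. All values are log2 intensities, and the number of arrays limits their precision. The median SD between arrays of a group was 0.207 in S0.5, 0.214 in ICI182R1, 0.218 in ICI164R4, 0.268 in ICI182R6 and 0.301 in ICI164R1.

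The actin transcript was measured near both ends on every array, and the difference between its ends (3′ minus 5′) parted the arrays into 2 sets. It was 2.0 to 4.43 in 9 arrays (ICI164R1 d and e, ICI182R6 d and e, and S0.5 2 to 6, the high set) and 0.186 to 1.07 in the other 17 (the low set, with S0.5 1). The controls of GAPDH (0.322 to 1.36 against -0.059 to 0.306), LysX (6.96 to 9.40 against 4.98 to 5.90) and PheX (7.66 to 10.0 against 5.84 to 7.26) parted the same arrays. The mean actin difference was 2.14 ± 1.01 (SD, n = 6) in S0.5, 1.73 ± 1.63 in ICI164R1, 1.87 ± 1.67 in ICI182R6, 0.324 ± 0.146 in ICI164R4 (exact permutation p = 0.0108, adjusted 0.0346) and 0.457 ± 0.0972 in ICI182R1 (exact permutation p = 0.0152, adjusted 0.0346; n = 5 in each subline). With 1 mean per group and the set in the fit, 146 genes were called higher and 144 lower in the high set than in the low set. All arrays of ICI164R4 and ICI182R1 are in the low set, so this difference rests on ICI164R1, ICI182R6 and S0.5.

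**Figure D1:**
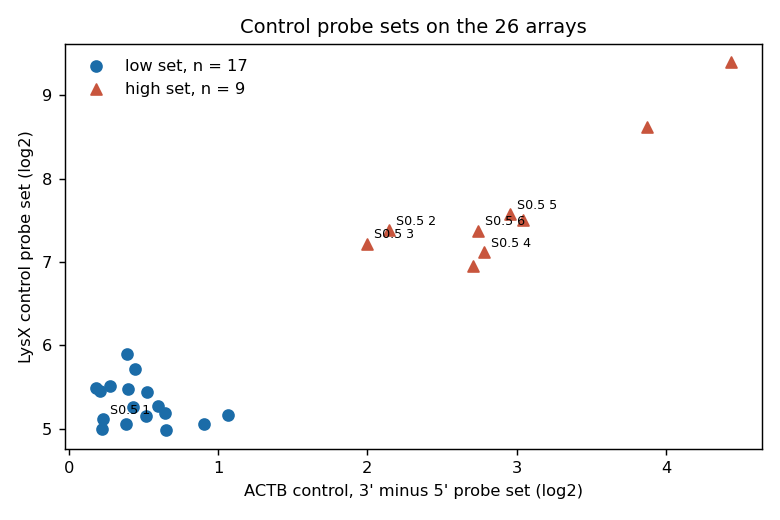
Control probe sets per array, in log2 units, for the 5 groups. The 9 arrays of the high set have actin differences of 2.0 to 4.43 and the 17 of the low set 0.186 to 1.07, and S0.5 has 5 arrays in the high set and 1 in the low set.

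CDK6, a kinase that pairs with D-type cyclins and phosphorylates RB, rose in the mean of the 4 sublines by 1.64 (SE 0.28, 3.12-fold, adjusted p = 0.00029). Its mean was 5.70 ± 0.26 (SD, n = 6) in S0.5, 7.60 ± 1.12 in ICI164R1, 7.65 ± 0.87 in ICI164R4, 7.09 ± 0.24 in ICI182R1 and 7.03 ± 0.30 in ICI182R6 (n = 5 each). All 20 resistant arrays lay above the S0.5 mean and 19 above every S0.5 array. CDK6 was called in each subline, with changes of 1.90, 1.95, 1.39 and 1.33 in the order ICI164R1, ICI164R4, ICI182R1 and ICI182R6. The kinase of the same family, CDK4, was at -0.27 (SE 0.10, adjusted p = 0.079, -0.41 with the block) and its partner CCND1 at -0.37 (SE 0.15, adjusted p = 0.099, -0.58 with the block), and neither was called. RB1, the substrate of both kinases, was at -0.65 (SE 0.17, adjusted p = 0.0089, below the S0.5 mean in 20 of 20 arrays), short of the fold threshold, and at -0.27 with the block. The CDK inhibitor CDKN2A was not called at 0.32 (SE 0.15), and at -0.05 with the block.

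With the block CDK6 was 1.73 higher (SE 0.36, adjusted p = 0.0047), but it was no longer called in all 4 sublines. Within the high set, with ICI164R1 and ICI182R6 alone, it was 1.71 higher (adjusted p = 0.0235), and within the low set, against 1 S0.5 array, 1.65 higher (adjusted p = 0.61). In the low set the spread comes from the resistant groups, and the lone S0.5 array is assumed to vary like them, in every result given for that set. Of the other CDK6 probe sets, without the block, 4 were called higher (3.01, 2.36, 3.26 and 1.15) and 2 were not (0.55 with adjusted p = 0.047, and 0.27 with adjusted p = 0.19). With the block 3 of the 4 stayed called (3.56, 2.48 and 3.01), the fourth was at 1.01 (adjusted p = 0.11), and the 2 not called were at 0.23 and 0.07. In the list of the cyclin D, CDK4/6 and RB axis, 1 of 22 measured genes was called higher (CDK6), 0 lower and 21 not, and the count adjusted over the list alone was also 1 (camera adjusted p = 0.51, adjusted p = 0.69 with an estimated correlation). At an unadjusted p under 0.05 in limma, 10 of the 22 passed. The next members by size, E2F5 at -0.99 (SE 0.20), E2F3 at -0.96 (SE 0.20, -0.39 with the block) and RBL2 at -0.86 (SE 0.19), fell short of the fold threshold. E2F5 passed it without any 1 of ICI164R4 a and b, ICI164R1 a and d, ICI182R1 e, ICI182R6 a and d, S0.5 1 and 6 (-1.10 to -1.0), and E2F3 without ICI164R1 e or S0.5 1 (-1.14 to -1.01).

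Few genes of the cell division cycle were called. In the list of proliferation and E2F targets, 0 of 30 genes were called higher, 1 lower and 29 not, with the same count adjusted over the list alone (median -0.25, camera adjusted p = 0.087, adjusted p = 0.69 with an estimated correlation). The gene called was CDC6, which licenses DNA replication, at -1.01 (SE 0.30, adjusted p = 0.021, below the S0.5 mean in 19 of 20 arrays). It was at -0.92 and not called with the block, and its call was lost without any 1 of ICI164R4 a and b, ICI164R1 a and c, ICI182R1 b and d, ICI182R6 a and e, S0.5 2 and 3 (values -1.0 to -0.93, adjusted p 0.0205 to 0.0634), with median centring (-0.96), with quantile normalization (-0.92) and with the mean of its probe sets (-0.84). The mitotic kinase PLK1 was at 0.90 (SE 0.36, adjusted p = 0.09) but at -0.40 with the block, and at 1.23 and called without S0.5 1. TYMS was at -0.78 (SE 0.16) and KIF20A at -0.62 (SE 0.20). With the block 0 genes of this list were called by limma (9 at an unadjusted p under 0.05), its median was -0.30 and its camera adjusted p 0.002 (adjusted p = 0.77 with an estimated correlation). The camera p of the list also passed without any 1 of ICI164R4 c and d, ICI182R1 e, S0.5 5 and 6 (adjusted p 0.024 to 0.0401).

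**Figure D2:**
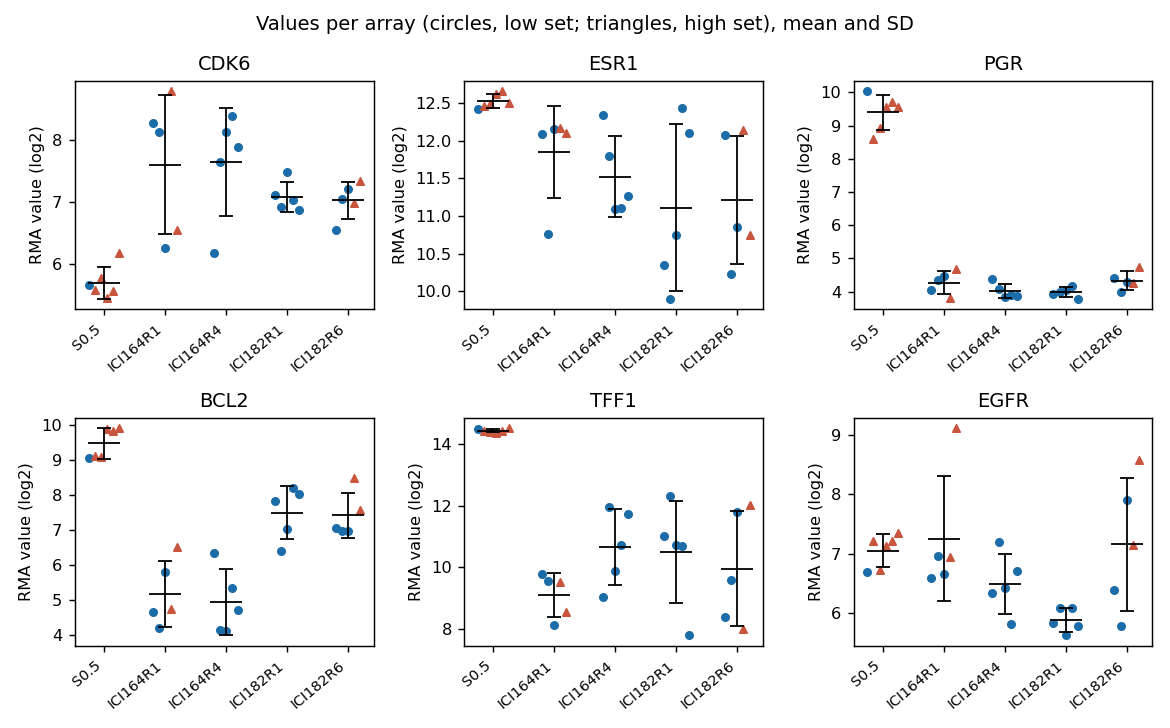
Log2 intensity of CDK6, ESR1, PGR, BCL2, TFF1 and EGFR on each array, by group, with the mean and SD; circles are arrays of the low set and triangles arrays of the high set. CDK6 is 5.45 to 6.18 in S0.5 and 6.18 to 8.79 in the resistant arrays, and PGR and BCL2 lie below every S0.5 array in all 20 resistant arrays.

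The progesterone receptor PGR, a classical target of the estrogen receptor, fell from 9.40 ± 0.53 (SD, n = 6) in S0.5 by 5.25 (SE 0.15, adjusted p = 1.8e-18). TFF1, a secreted protein under estrogen control, fell from 14.43 ± 0.06 by 4.38 (SE 0.54, adjusted p = 4.8e-06). Its S0.5 level was near the highest value on any array (15.13), and whether it was saturated, which would make the fall look smaller, was not tested. PDZK1, a scaffold protein, fell by 5.73 (SE 0.23), and PKIB, an inhibitor of protein kinase A, fell by 5.42 (SE 0.57). All 4 genes lay below every S0.5 array in 20 of 20 resistant arrays. The estrogen receptor gene ESR1 itself was 12.53 ± 0.10 in S0.5 and lower by far less, at -1.10 (SE 0.31, adjusted p = 0.015, below every S0.5 array in 19 of 20). Its call was lost with the block (-0.88, adjusted p = 0.21) and with the mean of its probe sets (-0.19). Within the low set ESR1 was at -1.09, and within the high set at -0.42 in ICI164R1 and -1.10 in ICI182R6.

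GREB1, another estrogen target, was not called on the probe set chosen by the rule (-0.22, SE 0.10, adjusted p = 0.13, -0.40 with the block), which was dim in S0.5 (5.48 ± 0.20). A brighter GREB1 probe set, picked after the values were seen, was at 9.89 ± 0.87 in S0.5 and at -6.26 in the sublines (SE 0.21, adjusted p = 2.8e-17). It was 3.15 to 4.21 on the resistant arrays, low intensities at which the S0.5 level limits the size of the fall. As the mean of its probe sets GREB1 was called at -2.54. In the list of the estrogen receptor and its targets, 0 of 38 genes were called higher, 23 lower and 15 not, with the same counts adjusted over the list alone (median -1.37, camera adjusted p = 2.1e-22, adjusted p = 6.5e-07 with an estimated correlation). With the block 22 were lower (NRIP1 in, ESR1 and CA12 out) and 1 higher, RET at 1.13, with a median of -1.34.

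BCL2, which blocks apoptosis and is also an estrogen target, fell from 9.46 ± 0.44 (SD, n = 6) in S0.5 by 3.21 (SE 0.33, 9.23-fold, adjusted p = 2.1e-07), below every S0.5 array in 20 of 20. The change was -4.27 in ICI164R1, -4.53 in ICI164R4, -1.97 in ICI182R1 and -2.05 in ICI182R6. With the block BCL2 was at -2.70 and no longer called in all 4 sublines. The other 3 BCL2 probe sets were at -0.96, -0.20 and -0.01 and not called, and the mean of its probe sets was called at -1.09. Of 11 anti-apoptotic genes 0 were called higher, 1 lower (BCL2) and 10 not, with the same counts adjusted over the list alone (camera adjusted p = 0.4, adjusted p = 0.69 with an estimated correlation). BAG1 was at -0.95 (SE 0.23, -0.59 with the block), and was called without ICI182R6 d or S0.5 1 (-1.06 to -1.0). BCL2L1 was at 0.64 (SE 0.10) and BIRC5 at -0.53 (SE 0.16, -0.10 with the block). FAS, a death receptor, rose by 1.67 (SE 0.22, adjusted p = 1.4e-05, above the S0.5 mean in 19 of 20). It was the 1 gene called higher of 21 pro-apoptotic genes, with 0 lower and 20 not, and the same counts adjusted over the list alone (camera adjusted p = 0.77, adjusted p = 0.85 with an estimated correlation). BAX was at -0.81 (SE 0.18, -0.52 with the block), BOK at -0.68 (SE 0.19, -0.30 with the block) and APAF1 at -0.47 (SE 0.14, -0.11 with the block). The medians of both lists (-0.02 for the pro-apoptotic, -0.10 for the anti-apoptotic) were near 0, and the camera direction for the pro-apoptotic list was up.

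Genes changed in the same direction in all 4 sublines included EPAS1, a hypoxia-inducible transcription factor, which rose by 3.66 (SE 0.49, 12.7-fold). CPNE4, a calcium-dependent membrane-binding protein, rose by 3.32 (SE 0.38), the lysosomal protein LAMP3 by 3.14 (SE 0.51), the adhesion molecule L1CAM by 3.02 (SE 0.47) and the transcriptional corepressor RUNX1T1 by 2.93 (SE 0.38). The immunoproteasome subunit PSMB8 rose by 2.73 (SE 0.33), PLAAT4 by 2.62 (SE 0.41), C3orf70 by 2.53 (SE 0.34), the peptide transporter TAP2 by 2.28 (SE 0.28), the viral receptor CXADR by 2.04 (SE 0.18), the microtubule protein MAP2 by 1.99 (SE 0.27) and the vasoactive peptide ADM by 1.97 (SE 0.30). TAP2 was at 0.98 as the mean of its probe sets.

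Among the 12 lowest genes of the rule were NPY1R, a neuropeptide Y receptor, at -6.80 (SE 0.22), PDZK1, PKIB, and the growth factor receptor IGF1R at -5.35 (SE 0.27). The others were PGR, the cytokine IL20 at -5.19 (SE 0.16), SYTL5 at -5.18 (SE 0.23), the GDNF co-receptor GFRA1 at -4.89 (SE 0.11, adjusted p = 1.2e-20), MPPED2 at -4.61 (SE 0.15), TFF1, the fatty acid elongase ELOVL2 at -4.28 (SE 0.14) and RBM24 at -3.94 (SE 0.19). On the resistant arrays NPY1R was 3.49 to 4.32, PDZK1 3.73 to 5.15, PGR 3.79 to 4.74 and MPPED2 3.41 to 4.38. For NPY1R, PGR and MPPED2 these are low intensities (the lowest value on any array was 2.8), at which the S0.5 level limits the size of the fall. By the rule that picked them, in each of these 24 genes all 20 resistant arrays lay beyond all 6 S0.5 arrays. Their direction against the single S0.5 array of the low set was thereby fixed. The sizes against that array were 1.55 to 4.47 for the higher genes and -6.47 to -3.28 for the lower genes.

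In total 47 genes were called higher and 114 lower in all 4 sublines (quantile normalization 73 and 102). In 21 of the higher and 74 of the lower genes no resistant array overlapped the S0.5 arrays. Over all 19775 genes, called or not, all resistant arrays lay above all S0.5 arrays in 53 and below them in 199, where chance gives 0.0859 genes in each direction. With the block, 43 were higher and 59 lower, 26 and 59 of them in common with the calls without it. LAMP3, PLAAT4, ADM, BCL2 and CDK6 were not among those kept in all 4, though each stayed called in the mean of the 4 sublines. The mean of the 4 sublines gave 256 higher and 263 lower genes (quantile normalization 301 and 210, median centring 292 and 228), and 185 and 128 with the block, of which 132 and 115 were in common and 516 of the 519 kept their sign. Within the low set, against 1 S0.5 array, 7 genes were called higher and 33 lower in the mean, and 2 higher and 24 lower in all 4 sublines. Within the high set 333 were called in the mean of ICI164R1 and ICI182R6.

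ICI164R1 had 206 genes higher and 326 lower than S0.5 (quantile normalization 260 and 264). The peroxisomal hydrolase NUDT7 rose there by 3.87 (SE 0.40), EPAS1 by 3.39 (SE 0.64), the interferon-induced OAS2 by 3.34 (SE 0.88, 3.02 and not called with the block) and CPNE4 by 3.31 (SE 0.50). The secreted protein CRISP3 was 3.87 higher (SE 1.13, adjusted p = 0.031), and its call was lost without any 1 of ICI164R1 c and e, S0.5 2 and 3 (values 3.10 to 3.79, adjusted p 0.0599 to 0.111). The lowest genes were NPY1R (-6.74), PDZK1 (-5.70), TFF1 (-5.33), IL20 (-5.25) and PGR (-5.13). With the block 215 were higher and 183 lower, sharing 155 and 174 with the calls without it. Within the high set 183 were higher and 186 lower, and within the low set 6 and 28.

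In ICI164R4, 317 genes were higher and 350 lower (quantile normalization 363 and 290, median centring 362 and 297). NUDT7 rose by 4.61 (SE 0.40), EPAS1 by 4.44 (SE 0.64), CPNE4 by 3.81 (SE 0.50) and LAMP3 by 3.55 (SE 0.66). CRISP3 was 4.12 higher (SE 1.13, adjusted p = 0.019, 5.21 with the block), a call lost without ICI164R4 a (3.30) or e (3.78). NPY1R fell by 6.89, PDZK1 by 5.85, PKIB by 5.55, PGR by 5.39 and IL20 by 5.23. All 5 arrays of this subline are in the low set with 1 S0.5 array. With the block 160 genes were higher and 91 lower, and 99 and 85 were in common. Within the low set 4 were higher and 29 lower.

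ICI182R1 gave 341 higher and 349 lower genes (quantile normalization 398 and 251, median centring 403 and 268). The chromatin organizer SATB1 rose by 4.79 (SE 0.55), the matrix protein EDIL3 by 4.77 (SE 0.51) and the mitochondrial kinase CMPK2 by 4.41 (SE 0.82). The interferon-induced IFI44L rose by 5.34 (SE 1.09, 4.73 and not called with the block) and IFI44 by 4.36 (SE 0.91, 3.94 and not called with the block). NPY1R fell by 6.66, PKIB by 5.67, SYTL5 by 5.64, IGF1R by 5.62 and PDZK1 by 5.48. This subline too lies in the low set alone. With the block 205 genes were higher and 103 lower, with 138 and 89 in common, and within the low set 11 were higher and 28 lower.

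For ICI182R6 the counts were 136 higher and 275 lower (quantile normalization 188 and 212). EDIL3 rose by 4.22 (SE 0.51), SATB1 by 3.06 (SE 0.55), the pyrimidine-degrading enzyme DPYD by 3.04 (SE 0.77) and EPAS1 by 2.99 (SE 0.64). SATB1 was at 1.39 and not called as the mean of its probe sets. CMPK2 was 3.21 higher (SE 0.82, adjusted p = 0.016), a call lost without ICI182R6 a (2.61, adjusted p = 0.0656). NPY1R fell by 6.90, PDZK1 by 5.90, IGF1R by 5.76, PKIB by 5.64 and SYTL5 by 5.57. With the block 152 were higher and 155 lower, with 103 and 145 in common. Within the high set 117 genes were higher and 118 lower, and within the low set 5 and 31.

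Some interferon-stimulated genes were called higher in the sublines, and most of these calls were lost with the block. IFI44L was 3.49 higher (SE 0.84, adjusted p = 0.0053, above the S0.5 mean in 17 of 20 arrays), IFI44 3.07 (SE 0.70, 18 of 20), OAS2, which makes an activator of RNase L, 2.97 (SE 0.68, 18 of 20) and its relative OAS1 2.76 (SE 0.40, adjusted p = 4.6e-05, 20 of 20). Of 30 such genes 21 were called higher, 0 lower and 9 not, and 24 higher when adjusted over the list alone (median 1.70, camera adjusted p = 1e-18, adjusted p = 0.18 with an estimated correlation). With the block 5 were called (OAS1 at 2.38, with OAS3, IRF9, UBE2L6 and PARP9), 18 when adjusted over the list alone, with a median of 1.54. IFI44L (3.03), IFI44 (2.75) and OAS2 (2.51) were not called with the block. IFI44L was at 4.09 in ICI164R1 and 3.06 in ICI182R6 within the high set, and at 0.89 in the mean of the sublines within the low set. In the low set IFI44 was at 0.49, OAS2 at 0.93 and OAS1 at 1.24. The SD of IFI44L between arrays was 1.36 in S0.5 and 3.03 in ICI182R6.

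Some genes that load peptides on MHC class I were called higher, with and without the block. PSMB9, a subunit of the immunoproteasome, rose by 3.10 (SE 0.50), the class I heavy chain HLA-C by 2.78 (SE 0.42), PSMB8 by 2.73 and TAP2 by 2.28, each above the S0.5 mean in 20 of 20 arrays. HLA-B, TAP1 and NLRC5, the activator of these genes, were also called. Of 15 genes in the list 7 were called higher, 0 lower and 8 not, with the same counts adjusted over the list alone and with the block (median 0.99, camera adjusted p = 1e-11, adjusted p = 0.18 with an estimated correlation).

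**Figure D3:**
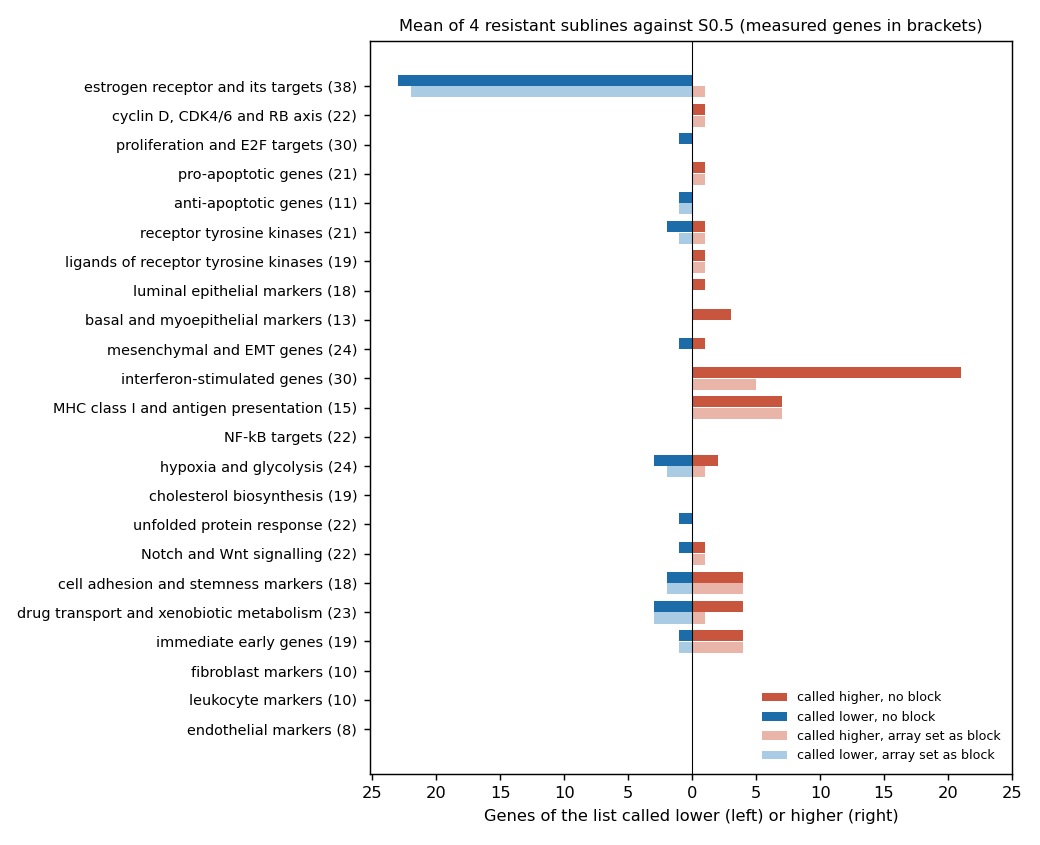
Number of genes of each fixed list called higher (bars to the right) or lower (bars to the left) in the mean of the 4 sublines against S0.5; dark bars are without the block and light bars with it. The estrogen receptor list has 23 genes lower (22 with the block) and the interferon list 21 higher (5 with the block).

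Among receptor tyrosine kinases IGF1R fell by 5.35. EGFR was not called on the probe set of the rule (-0.36, SE 0.31, adjusted p = 0.49), where it was at 0.30 with the block, and another EGFR probe set was at 1.12 (SE 0.28, adjusted p = 0.0082), or 0.78 with the block. ERBB2 was at 0.41 (SE 0.11, adjusted p = 0.011), short of the fold threshold. FGFR4 was lower at -1.41 (SE 0.34, -1.06 and not called with the block), and ERBB4 at -1.65 (SE 0.67, adjusted p = 0.096, -0.75 with the block) was not called. FGFR2 was higher at 1.27 (SE 0.40, adjusted p = 0.032, 17 of 20 arrays), not called with the block (1.15), and its call was lost without any 1 of S0.5 2 to 6 (values 1.22 to 1.32, adjusted p 0.0542 to 0.0764). As the mean of their probe sets FGFR4 was at -0.58 and FGFR2 at 0.54, and neither was called. Of 21 genes 1 was called higher, 2 lower and 18 not, and 1 and 3 when adjusted over the list alone (median 0.09, mean -0.26, camera direction up, adjusted p = 0.51, adjusted p = 0.69 with an estimated correlation). With the block 1 was higher (RET, in place of FGFR2) and 1 lower (IGF1R). The lymphangiogenic factor VEGFC was the 1 gene called higher of 19 ligands, with 0 lower, 18 not and the same counts adjusted over the list alone (camera adjusted p = 0.56, adjusted p = 0.69 with an estimated correlation). It was at 1.01 (SE 0.25, 20 of 20 arrays), and its call was lost without any 1 of ICI164R4 a and b, ICI164R1 b and d, ICI182R1 e, ICI182R6 d, S0.5 5 and 6 (values 0.92 to 0.99), and with quantile normalization (0.99). BTC was at -0.72 (SE 0.28, -0.36 with the block), ARTN at -0.62 (SE 0.13) and FGF7 at 0.40 (SE 0.25).

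Markers of epithelial type moved in single genes. Of 18 luminal genes 1 was called higher, 0 lower and 17 not, the same adjusted over the list alone (camera adjusted p = 0.51, adjusted p = 0.69 with an estimated correlation). That was the transcription factor ELF3 at 1.01 (SE 0.17, 20 of 20 arrays), which was at 0.82 and not called with the block, and lost its call without any 1 of ICI164R4 b, ICI164R1 a and d, ICI182R1 a and d, ICI182R6 b and c, S0.5 2 and 5 (values 0.97 to 1.0), and as the mean of its probe sets (0.84). ANKRD30A was at -0.82 (SE 0.34, -1.34 with the block), TFAP2C at -0.65 (SE 0.13) and FOXA1 at 0.46 (SE 0.25, -0.12 with the block). Of 13 basal genes 3 were called higher, 0 lower and 10 not, the same adjusted over the list alone (median 0.25, camera adjusted p = 0.00055, adjusted p = 0.14 with an estimated correlation). P-cadherin CDH3 was at 1.14 (SE 0.21, 18 of 20 arrays; 0.99 with the block), smooth muscle actin ACTA2 at 1.22 (SE 0.25, 19 of 20; 1.0 with the block) and the caveola protein CAV2 at 1.55 (SE 0.54, adjusted p = 0.048, 17 of 20; 1.70 with the block). As the mean of their probe sets ACTA2 was at 0.34 and CAV2 at 0.82, and neither was called. None of the 3 was called with the block, where limma called 0 of the 13 (4 at an unadjusted p under 0.05), 1 when adjusted over the list alone. Camera at the preset correlation then gave an adjusted p of 0.017, and no block value with an estimated correlation is given here. The call of CAV2 was lost without any 1 of 21 arrays, that is all but ICI164R4 a, ICI164R1 c, d and e and ICI182R1 e (values 1.45 to 1.58, adjusted p 0.0513 to 0.0908), and with quantile normalization (1.54, adjusted p = 0.0509). CAV1, at 1.66 (SE 0.71, adjusted p = 0.12), was called without ICI164R4 a or ICI164R1 e (1.88 and 1.89). Against S0.5 CDH3 was at 1.82 in ICI164 and 0.45 in ICI182, CAV2 at 2.55 and 0.55, and CAV1 at 3.37 and -0.06. Each was called in ICI164 alone.

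Of 24 mesenchymal genes 1 was called higher, 1 lower and 22 not, with the same counts adjusted over the list alone and a median of -0.01 against a mean of 0.05 (camera direction up, adjusted p = 0.51, adjusted p = 0.69 with an estimated correlation). SNAI2, a repressor of E-cadherin, was at 1.96 (SE 0.54, 19 of 20 arrays; 1.91 and not called with the block). The calcium-binding protein S100A4 was at -1.25 (SE 0.19, 20 of 20; -0.90 and not called with the block). FN1 was at -0.79 (SE 0.26) and TGFB2 at 0.70 (SE 0.48). With the block limma called 0 of the 24, with 3 at an unadjusted p under 0.05. Adhesion and stemness genes had 4 of 18 higher, 2 lower and 12 not, with the same counts adjusted over the list alone (camera adjusted p = 0.4, adjusted p = 0.69 with an estimated correlation). L1CAM rose by 3.02, SOX2, a pluripotency factor, by 2.02 (SE 0.54, 19 of 20 arrays; 0.72 as the mean of its probe sets), CEACAM6 by 1.51 (SE 0.34, 19 of 20) and SOX9 by 1.33, while the collagen receptor ITGA2 fell by 2.11 (SE 0.27, 20 of 20) and SOX4 by 1.32 (0.91 and not called with the block). SOX9 was at -0.03 in ICI164 and 2.7 in ICI182 against S0.5, and was called in ICI182 alone. With the block 4 were higher and 2 lower, with MYC (-1.20, or -0.95 without it) in place of SOX4.

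The lists held 3 aldo-keto reductases called lower, which act on steroids and drugs. AKR1C2 fell by 3.14 (SE 0.36), AKR1C1 by 2.51 (SE 0.37) and AKR1C3 by 2.21 (SE 0.39), below the S0.5 mean in 20, 20 and 19 of 20 arrays. AKR1C1 was at -0.99 as the mean of its probe sets. The drug-metabolizing oxidase CYP1B1 was at 2.01 (SE 0.53, 18 of 20; 1.96 and not called with the block), and ABCC3 at 1.46, AHR at 1.68 and AHRR at 1.08 were also called. AHR (1.81) and AHRR (0.99) were not called with the block. AHRR was at 1.7 in ICI164 and 0.45 in ICI182 against S0.5, and was called in ICI164 alone. Of 23 genes of drug transport and metabolism 4 were called higher, 3 lower and 16 not, the same adjusted over the list alone (median and mean below 0, camera direction up, adjusted p = 0.44, adjusted p = 0.69 with an estimated correlation). With the block 1 was higher and 3 lower.

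Hypoxia and glycolysis genes moved both ways. ADM rose by 1.97, the stress-induced NDRG1 fell by 1.45 (SE 0.18, 20 of 20 arrays) and the glucose transporter SLC2A1 fell by 1.05 (SE 0.15). EGLN3, an oxygen sensor, was at 1.15 (SE 0.40, adjusted p = 0.0497, 15 of 20), was at 1.37 and not called with the block, and lost its call without any 1 of 20 arrays, that is all but ICI164R4 a and b, ICI164R1 c and e, ICI182R1 d and ICI182R6 a (values 1.07 to 1.27, adjusted p 0.0512 to 0.106). The glycolytic regulator PFKFB3 was at -1.09 (SE 0.31, 17 of 20), and its call was lost with the block (-0.86), with quantile normalization (-0.98) and without S0.5 4 or 5 (values -1.0 to -0.96, adjusted p 0.0505 to 0.0566). Of 24 genes 2 were called higher, 3 lower and 19 not, the same adjusted over the list alone (median -0.35, camera adjusted p = 0.038, adjusted p = 0.65 with an estimated correlation). With the block 1 was higher and 2 lower, the median was -0.12 and the camera adjusted p 0.16. The camera call was also lost without any 1 of ICI164R4 b, ICI164R1 e, ICI182R1 d, S0.5 2 and 3 (adjusted p 0.0517 to 0.0689), and without the 30 percent of genes lowest in mean (0.0858).

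The MAP kinase phosphatase DUSP4 rose by 2.24 (SE 0.51, 19 of 20 arrays), PHLDA1 by 1.33 (SE 0.24, 20 of 20) and the ETS factor ETV5 by 1.32 (SE 0.36, 18 of 20; 0.72 and not called as the mean of its probe sets). The immediate early factor EGR1 was at 2.02 (SE 0.67, adjusted p = 0.04, 17 of 20) but at -0.25 with the block, -0.57 within the low set and 0.20 as the mean of its probe sets, and its call was lost without any 1 of ICI164R4 c, ICI164R1 a, b and c, ICI182R1 b, ICI182R6 a, b and c, and S0.5 2 to 6 (values 1.73 to 2.06, adjusted p 0.0509 to 0.123). Of 19 immediate early genes 4 were called higher, 1 lower (DUSP5 at -1.01, -0.68 and not called with the block) and 14 not, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.039, adjusted p = 0.67 with an estimated correlation). With the block 4 were higher, with DUSP6 (1.51, or 0.75 without it) in place of EGR1, 1 was lower, FOSB (-1.07, or -0.73 without it) in place of DUSP5, and the camera adjusted p was 0.23. The camera call was lost without any 1 of ICI164R4 b and c, ICI164R1 a, b and d, ICI182R1 b, ICI182R6 a, S0.5 1, 2 and 3 (adjusted p 0.0517 to 0.0918). It was also lost with the mean of probe sets (0.0528), without the 30 percent of genes lowest in mean (0.0532), with median centring (0.089) and with quantile normalization (0.0778).

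In Notch and Wnt signalling the Notch ligand DLL1 was at -1.24 (SE 0.24, 19 of 20 arrays; -1.0 and not called with the block). HEY1, a Notch target, was at 1.10 (SE 0.34, adjusted p = 0.028, 15 of 20; 1.51 with the block), and its call was lost without any 1 of S0.5 1, 4, 5 and 6 (values 1.03 to 1.10, adjusted p 0.0534 to 0.0655). As the mean of their probe sets DLL1 was at -0.58 and HEY1 at 0.87 (adjusted p = 0.057), and neither was called. HEY1 was at 0.44 in ICI164 and 1.75 in ICI182 against S0.5, and was called in ICI182 alone. NRARP was at -0.72 (SE 0.13, -0.37 with the block) and NOTCH3 at 0.67 (SE 0.20, 0.37 with the block). Of 22 genes 1 was called higher, 1 lower and 20 not, the same adjusted over the list alone (camera adjusted p = 0.088, adjusted p = 0.2 with an estimated correlation). CHAC1, which degrades glutathione, was the 1 gene called lower of 22 in the unfolded protein response, at -1.16 (SE 0.24, 19 of 20; -0.94 and not called with the block), with 0 higher, 21 not and the same counts adjusted over the list alone (camera adjusted p = 0.66, adjusted p = 0.85 with an estimated correlation). ASNS was at -0.68 (SE 0.39, -0.44 with the block), CALR at -0.65 (SE 0.23, 0.11 with the block) and HSPA5 at 0.55 (SE 0.11).

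Limma called 0 of 22 NF-kB targets, also when adjusted over the list alone, with 6 at an unadjusted p under 0.05 (median 0.08, camera adjusted p = 0.01, adjusted p = 0.14 with an estimated correlation, and adjusted p = 0.18 with the block). IL1A was at 0.99 (SE 0.33, 0.13 with the block), and was called without any 1 of ICI164R4 b and c, ICI164R1 d and e, ICI182R1 a and c, ICI182R6 d and e and S0.5 1 (1.01 to 1.15), and with median centring (1.03). SOD2 was at -0.72 (SE 0.39, 0.47 with the block), NFKB2 at 0.57 (SE 0.16, 0.19 with the block) and TNFAIP3 at 0.54 (SE 0.19). In cholesterol biosynthesis limma called 0 of 19, also when adjusted over the list alone, with 8 at an unadjusted p under 0.05 (median 0.05, camera adjusted p = 0.087, adjusted p = 0.69 with an estimated correlation). The camera p passed without ICI164R4 a (0.0333) or ICI182R1 d (0.0384), with the mean of probe sets (0.0376) and with quantile normalization (0.0436). SQLE was at 0.75 (SE 0.18), SC5D at 0.70 (SE 0.19), TM7SF2 at 0.67 (SE 0.27, -0.04 with the block) and STARD4 at -0.62 (SE 0.27).

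Markers of other cell types were not called, also when adjusted over the list alone. Limma called 0 of 10 fibroblast genes (1 at an unadjusted p under 0.05; COL1A1 at -0.43, SE 0.09), with a camera adjusted p of 0.56 (adjusted p = 0.69 with an estimated correlation). It called 0 of 10 leukocyte genes (1 at an unadjusted p under 0.05; LYZ at -0.21, SE 0.07, and -0.12 with the block), with a camera adjusted p of 0.51 (adjusted p = 0.69 with an estimated correlation). It called 0 of 8 endothelial genes (1 at an unadjusted p under 0.05), with a camera adjusted p of 0.18 (adjusted p = 0.53 with an estimated correlation). PECAM1, named by the size of its change, was at 0.20 (SE 0.11, and 0.01 with the block) and was not the gene under 0.05.

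The sublines shared many of their changed genes. Pairs of sublines had 62 to 156 higher and 144 to 195 lower genes in common, where independent lists would share 1.42 to 5.47 and 4.53 to 6.18. All 4 contrasts use the same S0.5 arrays. Simulated groups without change, which also used shared S0.5 arrays, gave correlations across genes of 0.451 to 0.458 against 0.669 to 0.837 between the sublines. The simulation held no effect of the array set, which could raise the correlations and the shared calls in the real arrays. It is therefore no baseline for that effect. With the block the correlations between the sublines were 0.626 to 0.811, and no simulated value goes with that fit. Genes are not independent replicates. When each subline of a pair was set against a separate group of 3 S0.5 arrays, the mean number shared was 141.2 (36.9 higher and 104.3 lower) against 274.5 (103.2 and 171.3) with all 6, and 184.8 with 3 arrays used for both. The correlations across genes were then 0.58 to 0.75. For all 4 sublines independent lists would share 0.000392 higher and 0.00142 lower genes, where 47 and 114 were seen.

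The ICI182 and ICI164 families, named in the series design, were compared to find where their changes differed. EDIL3 was 4.30 higher in ICI182 than in ICI164 (SE 0.37, adjusted p = 7.4e-08), with changes against S0.5 of 4.49 and 0.19. SATB1 was 3.84 higher (SE 0.41), the breast antigen ANKRD30A 3.76 (SE 0.33), the non-coding LINC00993 2.70 (SE 0.27), the membrane protein TMC5 2.41 (SE 0.21), the collagen COL12A1 2.19 (SE 0.41), the NF-kB subunit REL 1.59 (SE 0.19) and the oxidase QSOX1 1.40 (SE 0.18). ANKRD30A was lower than S0.5 in ICI164 (-2.69) and not called in ICI182 (1.06). NUDT7 was lower in ICI182 by -3.68 (SE 0.29), with changes of 4.24 in ICI164 and 0.56 in ICI182. The scaffold protein SASH1 was at -2.89 (SE 0.23), the glycosyltransferase GALNT12 at -2.84 (SE 0.35), the homeobox factor DLX2 at -2.79 (SE 0.23), fibronectin FN1 at -2.72 (SE 0.25), the water channel AQP3 at -2.39 (SE 0.30), DLX1 at -1.82 (SE 0.13, adjusted p = 6.6e-09) and the GABA receptor GABBR2 at -1.5 (SE 0.16). By the rule that picked them, in each of these 16 genes all 10 arrays of a family lay beyond all 10 of the other.

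**Figure D4:**
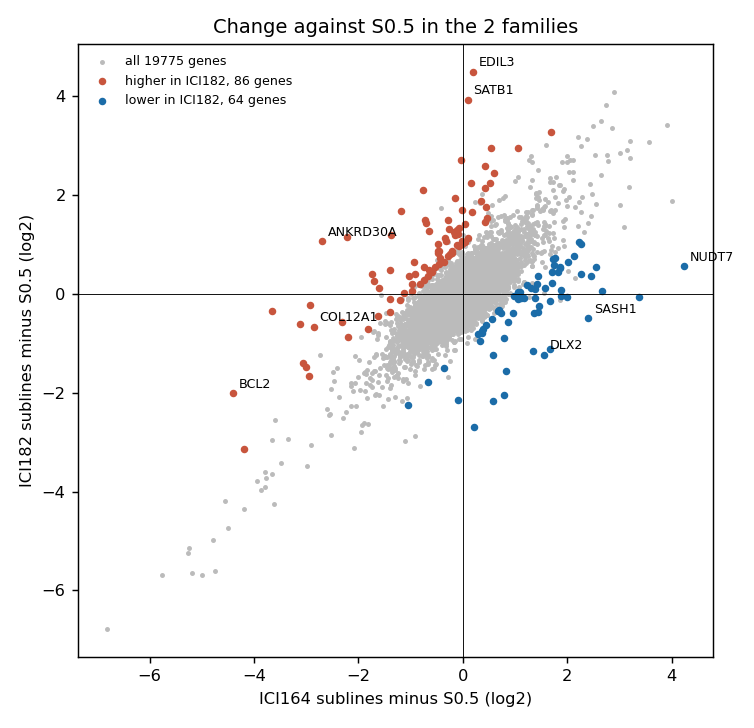
Log2 change against S0.5 of each gene in the ICI164 sublines (horizontal) and the ICI182 sublines (vertical), with the 86 genes called higher in ICI182 than in ICI164 in red and the 64 called lower in blue. DLX2 is 1.56 higher in ICI164 and at -1.23 in ICI182, and ADGRL2 is at -1.18 and 1.68.

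In total 86 genes were higher and 64 lower in ICI182 than in ICI164, and all 150 stayed called with the block (92 and 69). Each family has 2 arrays in the high set, so the block left these differences as they were and changed only their spread. Keeping the calls is therefore no test of the array set. With array weights the counts were 80 and 92. Without ICI164R4 a, ICI164R1 c and ICI164R1 e, picked after their values were seen, they were 79 and 142. Within the low set 113 were called and within the high set 48. In 11 genes higher and 9 lower the arrays of the families did not overlap. Over all 19775 genes, called or not, this held for 12 higher and 22 lower, where chance gives 0.107 genes in each direction. Against S0.5 the ICI164 family had 271 higher and 328 lower genes (217 and 141 with the block, quantile normalization 334 and 259, and 9 and 33 within the low set). The ICI182 family had 263 higher and 286 lower (225 and 126 with the block, quantile normalization 314 and 225, and 9 and 33 within the low set). Both families shared 305 genes in the same direction and 2 in opposite directions, ADGRL2 and DLX2. Of 292 genes called in ICI164 alone 54 were called different between the families, and of 242 in ICI182 alone 42 were. Of the 150 different genes 46 were called against S0.5 in neither family.

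BCL2 was 2.39 higher in ICI182 than in ICI164 (SE 0.31, adjusted p = 3.7e-05), or 0.76 as the mean of its probe sets. This difference includes ICI164R4 a, ICI164R1 c and ICI164R1 e, where BCL2 was 6.35, 5.8 and 6.51 against 4.12 to 5.35 on the other 7 ICI164 arrays. CDK6 was not called different (-0.57, SE 0.27, adjusted p = 0.28). This value includes ICI164R4 a, ICI164R1 c and ICI164R1 e, on which CDK6 was 6.18, 6.26 and 6.56 against 7.65 to 8.79 on the other 7 ICI164 arrays. No difference without these 3 is given, since they stand apart in CDK6 itself. It was not called without any 1 of them (-0.75 to -0.70). Of the lists, interferon-stimulated genes alone passed camera (median 0.39, adjusted p = 0.0019, adjusted p = 0.9 with an estimated correlation). Limma called 0 of its 30 genes (4 at an unadjusted p under 0.05), and 1, BST2 at 1.49, with the block (adjusted p = 0.0317), without the 30 percent of genes lowest in mean (adjusted p = 0.0412), with median centring (1.51, adjusted p = 0.0487) and with quantile normalization (1.52, adjusted p = 0.0445). BST2 was also called without any 1 of ICI164R4 c, ICI164R1 a and b, ICI182R1 b, ICI182R6 c and e and S0.5 1, and was not called without ICI164R4 a, ICI164R1 c and ICI164R1 e together (0.87, adjusted p = 0.241). That camera call was lost without any 1 of ICI182R1 a and e, ICI182R6 a and d (adjusted p 0.0505 to 0.122). With the preset correlation, which alone was used when single arrays were left out, the camera p passed for 4 more lists. These were proliferation (without ICI164R4 c or d or ICI182R1 d, adjusted p 0.00128 to 0.0173), MHC class I (without ICI164R4 c, ICI182R1 b or c, or ICI182R6 c or e, adjusted p 0.00291 to 0.0493), NF-kB targets (without ICI164R4 c or ICI164R1 b, adjusted p 0.0365 to 0.0493) and Notch and Wnt signalling (without ICI164R4 c, adjusted p = 0.0493). Other list members were called between the families.

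Higher in ICI182 than in ICI164 were the Notch ligand JAG1 by 2.12 (SE 0.49), HEY1 by 1.31 (SE 0.33), the transcription factor SOX9 by 2.73 (SE 0.37), the receptor TGFBR2 by 1.86 (SE 0.27) and the growth regulator RERG by 1.05 (SE 0.27). Lower were the caveola proteins CAV1 (-3.43, SE 0.68) and CAV2 (-2.0, SE 0.51), CDH3 (-1.37, SE 0.20), the receptors FGFR3 (-1.44, SE 0.29) and RET (-1.08, SE 0.23), the CDK inhibitor CDKN1A (-1.09, SE 0.17), CREB3L2 (-1.12, SE 0.20) and AHRR (-1.26, SE 0.27). The call of RERG was lost without any 1 of ICI164R4 b and c, ICI164R1 d, ICI182R1 c and d, ICI182R6 b and d (values 0.90 to 1.0), that of RET without ICI182R1 b or d (-0.98), that of CAV2 without ICI164R4 c or ICI164R1 a (-1.86 to -1.80) and that of CREB3L2 without ICI182R6 a (-0.97). Without ICI164R4 a, ICI164R1 c and ICI164R1 e together, JAG1 (1.47, adjusted p = 0.0629) and HEY1 (1.01, adjusted p = 0.0943) were not called. FGFR3 (-0.75), RET (-0.94), CREB3L2 (-0.46) and RERG (0.98) were not called as the mean of their probe sets. RET and RERG were the 1 gene lower and 1 higher of the estrogen receptor list, CDKN1A the 1 of the cyclin list, BCL2 the 1 of the anti-apoptotic list, and FGFR3 and RET the 2 receptor kinases. Limma called 0 genes in the lists of proliferation, pro-apoptotic genes, ligands, MHC class I, NF-kB targets, hypoxia, cholesterol, immediate early genes, fibroblasts, leukocytes and endothelium. At an unadjusted p under 0.05 the numbers in these lists were 4, 6, 3, 1, 2, 7, 3, 1, 2, 2 and 0.

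Sublines of the same family were compared to see how far they differed from each other. ICI164R4 and ICI164R1 had no gene called different by limma (0 of 19775, with 1937 at an unadjusted p under 0.05), and neither did ICI182R6 and ICI182R1 (0, with 1748). With the block the counts were again 0, with 2109 and 2271 at an unadjusted p under 0.05. NUDT7 was 9.19 ± 1.08 (SD, n = 5) in ICI164R1 and 9.92 ± 0.86 in ICI164R4, and EDIL3 was 9.94 ± 1.32 in ICI182R1 and 9.39 ± 0.87 in ICI182R6. Calls appeared when single arrays were left out, with up to 6 genes in the ICI164 pair without ICI164R1 a and up to 2 in the ICI182 pair without ICI182R1 e.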

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

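The family comparison and the actin and GAPDH controls were chosen before the values were seen, and the LysX and PheX controls afterwards. Single arrays were compared with the other arrays of their group, and a rule of this kind marks an array by chance in about 1 of 20 groups. It marked arrays in 16 of 195 groups.

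For the named genes, RB1 was 9.38 on S0.5 1 (9.81 to 10.05 on the other S0.5 arrays) and CDKN2A was 6.64 on ICI182R1 b (6.19 to 6.29 on the others). ESR1 was 10.76 on ICI164R1 b against 12.09 to 12.17, and EGFR 9.12 on ICI164R1 e against 6.59 to 6.96. EPAS1 was 7.86 on ICI182R6 a and 5.6 on S0.5 1. L1CAM was 7.33 on ICI164R4 a against 10.45 to 10.86. C3orf70 was 6.66 on ICI164R1 b and 8.88 on ICI182R6 d, and CXADR was 8.38 on ICI182R1 a. IGF1R was 4.67 on ICI182R6 d and SYTL5 4.86 on ICI182R6 e.

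Of the controls, S0.5 1 had an actin difference of 0.23, a LysX of 5.11 and a PheX of 6.48, and ICI164R4 e had a GAPDH difference of 0.12. S0.5 1 is the 1 S0.5 array of the low set.

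The change against S0.5 differed between the ICI182 and ICI164 families in 150 genes. The largest that separated all arrays were EDIL3 (4.30), SATB1 (3.84), ANKRD30A (3.76), LINC00993 (2.70), TMC5 (2.41), COL12A1 (2.19), REL (1.59), QSOX1 (1.4), NUDT7 (-3.68), SASH1 (-2.89), GALNT12 (-2.84), DLX2 (-2.79), FN1 (-2.72), AQP3 (-2.39), DLX1 (-1.82) and GABBR2 (-1.5). BCL2 differed by 2.39.

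Among probe sets annotated to several genes or to none, 33 were called in all 4 sublines (10 higher and 23 lower). With the block 1 was higher and 12 lower.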

How the results depend on the processing

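The array-set block, the fits within a set, the block without S0.5 1, the fits without 3 ICI164 arrays and the probe set with the highest group mean were chosen after the results were seen, and the other settings were set beforehand. For calls that were not kept the cause was not tested.

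With the mean of all probe sets of a gene, 396 genes were called in ICI164 and 97 between the families. Directions turned for EGFR (0.119), FOXA1 (-0.019), THY1 (0.008), CD79A (0.023) and PECAM1 (-0.003) in the mean of the 4 sublines, and for COL1A1 between the families (-0.022). Of the named genes and list members 232 kept their result, 20 were weaker and 1 stronger. With the probe set of highest group mean THY1 was at 0.3, and CD163 between the families at 0.008. The CDK6 probe sets that were not called were at 0.548 and 0.275.

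The treat test at a log2 change of 1 called 53 genes in ICI164R1, 43 in ICI164R4, 54 in ICI182R1, 31 in ICI182R6, 57 in ICI164, 58 in ICI182, 60 in the mean of the 4 sublines, 25 in all 4 and 12 between the families. A fold threshold of 1.5 gave 1402, 1733, 1694, 1165, 1802, 1679, 1667, 379 and 445 in the same order. The treat calls in all 4 were 0 higher and 25 lower, and in the mean 14 and 46. Array weights gave 760 in ICI182R6 and 263 in all 4.

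With the array set as a block, 251 genes were called in ICI164R4, 308 in ICI182R1, 358 in ICI164, 351 in ICI182, 313 in the mean of the 4 sublines and 102 in all 4. With the block and without S0.5 1 the mean gave 198 and all 4 gave 86. Directions turned with the block for CDKN2A (-0.048), EGFR (0.296), PLK1 (-0.399), FOXA1 (-0.116), SOD2 (0.469), TM7SF2 (-0.044), CALR (0.107), EGR1 (-0.249), FCER1G (-0.083), EMCN (0.046) and TEK (-0.047). Of the named genes and list members 225 kept their result with the block, 21 were weaker and 2 stronger.

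Within the low set, with 1 S0.5 array, 34 genes were called in ICI164R1, 33 in ICI164R4, 39 in ICI182R1, 36 in ICI182R6, 42 in ICI164, 42 in ICI182, 40 in the mean of the 4 sublines and 26 in all 4, and CDK6 was at 1.65 and not called. Directions turned there for CDKN2A (-0.025), PLK1 (-0.297), SOD2 (0.535), EGR1 (-0.574), COL6A3 (0.054), LYZ (0.034), PECAM1 (-0.004) and EMCN (0.512). Within the high set 235 genes were called in ICI182R6 and 48 between the families, and 333 in the mean of ICI164R1 and ICI182R6. Without the 3 ICI164 arrays (ICI164R4 a, ICI164R1 c and e) FGFR2 between the families was at -0.231. Of the named genes and list members 240 kept their result there, 13 gained a call and 5 lost it (CRISP3, CDC6, PFKFB3, JAG1 and HEY1). Those gained in the mean of the 4 sublines were E2F3 (-1.04), CAV1 (2.45) and TGFB2 (1.19). Among those gained between the families were DKK1 (-3.16), SOX2 (-1.73), AGR2 (-1.63), PFKFB3 (-1.20), TM7SF2 (-1.21), ITGA6 (1.19), EGF (1.09), CA12 (1.02) and ABCC3 (-1.01). The family value of CDK6 is not given for this setting, since these arrays stand apart in CDK6 itself. Separate groups of 3 S0.5 arrays shared 141.2 genes between sublines.

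Leaving out each array in turn gave 1.569 to 1.739 for CDK6 and 132 to 191 genes in all 4. The counts were 416 to 691 in ICI164R1, 531 to 876 in ICI164R4, 571 to 860 in ICI182R1, 322 to 568 in ICI182R6, 523 to 760 in ICI164, 485 to 661 in ICI182 and 452 to 648 in the mean of the 4 sublines. They were 131 to 168 between the families, 0 to 6 between ICI164R4 and ICI164R1 and 0 to 2 between ICI182R6 and ICI182R1.

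The replicate letters were tested as a block on the 20 resistant arrays. With this replicate block 114 genes were called between the families, against 117 without it, and 0 in each pair of sublines. RERG (1.05, adjusted p = 0.093), CAV2 (-2.0, adjusted p = 0.0946) and HEY1 (1.31, adjusted p = 0.0595) were not called there, with changes as in the 26 arrays. That fit differs in the block and in the number of arrays, which were not told apart for these genes. Arrays with the same letter had a median correlation of -0.014 over 30 pairs (-0.393 to 0.512, with 10 above 0.1), and 1 of 20 arrays matched its own letter best. Between ICI164R1 and ICI182R6 the letters a to e were at -0.122, 0.23, 0.255, 0.512 and 0.353. With the array set removed they were at -0.247, -0.057, 0.086, 0.219 and 0.19.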

Other observations

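The tests of array splits were set before their results were seen, and the other tests in this part were chosen afterwards. The genes in the next paragraph were chosen after their values were seen.

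Between the families, the chemokine receptor CXCR4 was 2.56 higher in ICI182 than in ICI164 (SE 0.57). Against S0.5 it was at 1.19 and -1.37, and neither change was called. The death ligand TNFSF10 was 1.90 higher (SE 0.37), the guanylate-binding proteins GBP1 by 1.58 (SE 0.45) and GBP2 by 1.42 (SE 0.23), and the Wnt carrier WLS by 2.10 (SE 0.32). The immune checkpoint ligand VTCN1 was 2.08 higher (SE 0.35) and the potassium channel KCNK2 2.87 higher (SE 0.39). The helix-loop-helix factor ID1 was at -2.91 (SE 0.72), the bone morphogenetic protein BMP7 at -1.86 (SE 0.28) and IGFBP3 at -1.18 (SE 0.26). SGCE (-2.60, SE 0.60), PEG10 (-1.92, SE 0.56) and PPP1R9A (-2.11, SE 0.34), which are 12, 13 and 14 genes from CDK6 in gene order, were higher in ICI164, at 2.66, 1.88 and 2.46 against S0.5.

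The set of arrays could have given the calls common to the 4 sublines, since 5 of 6 S0.5 arrays lie in the high set. The effect of the set seen inside ICI164R1 and ICI182R6 would give -6.3% of the median change of the higher genes and 12.4% of the lower genes. For the genes that the block did not keep it would give 4.8% and 29.1%. If the set acts on S0.5 as it does inside these sublines, it was not the whole cause of the common changes. That effect rests on 2 high-set arrays in each subline, and whether it carries over to S0.5 was not tested. LysX was 8.625 and 9.395 on their e arrays and 7.505 and 6.956 on their d arrays, against 7.12 to 7.57 on S0.5 2 to 6. All 161 genes kept their sign with the block.

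In 3 ICI164 arrays CDK6 was near the S0.5 level of 5.45 to 6.18: ICI164R4 a at 6.18, ICI164R1 c at 6.26 and ICI164R1 e at 6.56, against 7.65 to 8.79 on the other 7. The same 3 were also apart in BCL2 (5.8 to 6.51 against 4.12 to 5.35), toward S0.5. PGR lay the same way by a narrow gap at low intensities (4.37 to 4.68 against 3.82 to 4.36). In TFF1 the 3 were apart in the direction away from S0.5 (8.14 to 9.04 against 9.52 to 11.97). PDZK1 also lay away from S0.5 (3.89 to 4.03 against 4.03 to 4.69). The 3 overlapped the other 7 in NPY1R (3.73 to 4.14 against 3.64 to 3.98), IGF1R (4.82 to 6.05 against 4.1 to 6.67) and ESR1 (12.1 to 12.35 against 10.76 to 12.17). S0.5 cells or RNA in these samples could lower CDK6, but the highest PGR on the 3 was 4.68 against at least 8.61 in S0.5, which excluded it. The set of arrays was excluded too, as 2 of the 3 lie in the low set. Other technical differences were not tested. ICI164R1 c and e had the narrowest interquartile ranges of the 26 arrays (2.923 and 2.843), and ICI164R4 a had 3.188. The BioB control was 10.261 and 10.579 on ICI164R1 c and e and 8.141 on ICI164R4 a. It was 10.695 on ICI182R6 e and at most 9.281 on all other arrays. The cause remains open.

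Arrays of a family did not group by subline. In ICI164 the mean correlation was -0.123 within sublines and -0.0934 between them (exact p = 0.571), and in ICI182 it was -0.089 and -0.124 (exact p = 0.278). Other splits of the same arrays, 5 against 5, gave up to 215 genes in ICI164 and 178 in ICI182 (median 0). Arrays of this number can thus pass the thresholds, and small differences between sublines stay open. No reference value for such a maximum was made, so too few arrays to show a real subline difference were not excluded. With the set in the fit other splits still gave up to 212 and 203 (median 0). Calls thus arose with the set in the fit, but without a reference value the set was not excluded as their source. A wrong subline name on single arrays was not tested and stays open.

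A gain of DNA spanning the genes around CDK6 was tested as a cause of its higher level in ICI164. The 20 nearest genes with a mean above 6 had a median change of 0.001 with the block, which excluded a gain across all of them as the whole cause. PEG10 was 1 of these 20. SGCE (mean 5.06) and PPP1R9A (mean 5.18) were left out for their low mean. Over the 20 nearest genes of any mean, which reach 10 places to each side and so hold none of these 3, the median was 0.122, at percentile 93.2 of such windows. A gain of CDK6 alone or of a part of these genes stays open.

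For each contrast the arrays were also split in 100 ways, the real one included, and the splits with as many genes were counted. A chance split of single arrays was excluded for ICI182R1 (1 split; 690 genes, highest other 180), ICI182 (1; 549 and 200) and the mean of the 4 sublines (1; 519 and 164). It was also excluded for all 4 sublines (1; 161 and 0) and the families (1; 150 and 21). The splits moved single arrays, and each family has 2 sublines. Chance differences between sublines were therefore not tested. For ICI182R6 (411 genes) and ICI164 (599 genes) also only 1 of the 100 splits, the real one, gave as many. Other splits came close, with 408 where S0.5 1 was exchanged with ICI182R6 d and 559 where it was exchanged with ICI164R1 e. These nearly parted the array sets, with 4 low and 1 high against 0 low and 6 high arrays in ICI182R6. In ICI164 it was 9 low and 1 high against 0 and 6. In ICI164R1 (532 genes) only the real split gave as many. Its highest other split, with 319, exchanged S0.5 1 with ICI164R1 e, leaving 4 low and 1 high against 0 and 6. No verdict on chance is drawn for the counts of ICI164R1, ICI182R6 and ICI164. For contrasts against S0.5 the splits do not tell a subline from the array set. In ICI164R4 2 splits gave as many, the real one with 667 and another with 697, which was the split into the low and high sets (S0.5 1 with ICI164R4 against S0.5 2 to 6), and the ICI164R4 count with the block was 251. Between ICI164R4 and ICI164R1 and between ICI182R6 and ICI182R1 the real split gave 0 genes, so all 100 splits had to give at least as many and the count decides nothing. The highest other splits gave 215 and 178, but the median of the other splits was 0, and 13 and 18 of them gave any gene. No reference value for such a maximum was made, so it decides nothing about a structure apart from the subline names.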
